A study of Homo sapiens with 4 samples.

How the data were processed

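Total RNA from 4 cultures of the breast carcinoma line MDA-MB-231 was hybridised to Affymetrix U133 Plus 2 arrays, 1 array per culture. The groups, taken from the sample titles, were an shRNA vector control, a stable shRNA knockdown of ZEB2, an siRNA control against luciferase, and a transient siRNA pool against ZEB2. The deposited values are log2 expression values per probe set, made by the authors with RMA in the affy package, per the submitters' processing notes, whose versions were not given in the sources used here. RMA corrects the background, normalises the arrays to a common distribution and summarises the probes of each probe set. The sorted values of the 4 arrays lay within 0.0805 of their mean, so the arrays shared 1 distribution as deposited. This forces similar overall levels on the arrays and hides any change in total RNA per cell. No scanner files were used here, so background and detection per probe were not analysed here, and 0 columns of other series were present.

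Of the 54675 probe sets, 41097 carried 1 gene symbol in the platform annotation, 1801 carried several and 11777 had none in the table used here. Gene identifiers of 41043 of the first kind were found in the RefSeq table of GRCh38.p14, used for names alone, and 0 symbols needed updating. A gene was represented by its brightest probe set, by mean over the 4 arrays, among those with exactly 1 symbol, which gave 19775 genes. A gene was kept when its highest value over the 4 arrays reached the 40th percentile of all values, 4.77. This left 15082 genes and removed 4693. Differences of dim genes are compressed toward 0 by RMA, and an array value gives no absolute amount of RNA.

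Each knockdown was compared with its own control as a difference of log2 values. With 1 array per group no test within a pair exists, so genes were counted at 2-fold, with 1.5-fold and 3-fold as alternatives. Nothing in the labels says that the 2 pairs came from parallel cultures. The counts shared by the pairs were set beside n1 × n2 / N for independent lists. The only test was limma (version 3.58.1, in R 4.3.3), with lmFit and eBayes with an intensity trend, 2-sided, with knockdown as the effect and the method as a block, and Benjamini-Hochberg adjustment over all genes kept at 0.05. It takes its error from 1 residual degree of freedom, the gap between the pairs, moderated across genes, so its p-values measure the spread between the 2 methods and not between repeated cultures.

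The design, the named-gene rule, the processing alternatives and 24 gene lists holding 596 genes were fixed before the data were examined. Of the list genes, 48 had no probe set named in the table used here and were not analysed here. The median difference of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile describes these arrays alone. The percentiles 2.5 and 97.5 bound the central range. Genes named in the text were ZEB2, the 12 highest and 12 lowest by the smaller difference among genes with the same sign in both pairs, the 6 highest and 6 lowest of each pair, the 5 each way with the largest opposite differences, and the 5 highest and 5 lowest between the controls. Every gene of the core EMT panel was added, and from each other list its members at 2-fold the same way in both pairs or past the limma test, otherwise the 2 with the largest mean difference.

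Alternatives were the mean of all probe sets per gene, each probe set on its own, no cross-hybridising probe sets (names ending in _x_at), no filter, a filter at the 60th percentile or on the mean, median centring, quantile normalization and cyclic loess. For the common test there were also no method block, no trend and robust moderation. The limma step was tested on simulated data for 15082 genes. With the spread of the 4 arrays it recovered 0% of genes changed 2-fold and made 2 false calls. With the spread of the siRNA pair alone, set equal for every gene, it recovered 98.5% of genes changed 2-fold with 11 false calls. The latter setting is milder than these arrays, so its rate does not carry over to them. Of 100 simulated lists with no shift, 8 fell outside the central 95% of random lists, and 97 of 100 lists shifted by 0.2 lay above it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.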

Results

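Gene expression was profiled on 4 Affymetrix U133 Plus 2 arrays, which carry 54675 probe sets for human transcripts. All RNA came from MDA-MB-231, a human breast carcinoma line of the triple-negative, mesenchymal-like type. The study lowered ZEB2, a zinc-finger transcriptional repressor that drives epithelial-mesenchymal transition (EMT), in 2 ways. A stable knockdown used a short hairpin RNA (shRNA) delivered by a lentiviral vector, beside cells carrying the vector control pLVTH. A transient knockdown used a pool of small interfering RNAs (siRNA) at 20 nM, beside cells given siRNA against luciferase, a gene that human cells lack. The transfected cells were washed after 24 hours and harvested after a further 48 hours in culture medium. Each of the 4 groups had 1 array, so no difference within a pair has a replicate check, and the number of arrays limits the precision of every value. Differences below are knockdown minus control on the log2 scale, and 1 unit is 2-fold. Median log2 values of the arrays lay between 5.34 and 5.37. After genes that were dim on every array had been left out, 15082 genes remained.

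ZEB2 itself was lower in both knockdowns. Its brightest probe set read 6.12 in the shRNA control and 3.52 in the shRNA knockdown, 6.05-fold lower. The same probe set read 6.56 in the siRNA control and 3.51 in the siRNA knockdown, 8.28-fold lower. The next brightest ZEB2 probe set differed by -1.33 in the shRNA pair and by -1.50 in the siRNA pair. The remaining 3 ZEB2 probe sets stayed under the filter level of 4.77 on every array and differed by 0.09, 0.13 and 0.03 in the shRNA pair and by -0.08, 0.42 and 0.02 in the siRNA pair. ZEB2 was thus lower on both arrays labelled as knockdowns in the probe sets bright enough to read it. After knockdown the brightest probe set was itself under the filter level, where RMA compresses differences.

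The stable knockdown was compared with its vector control to find the genes that differ when ZEB2 is kept low in an established line. The highest differences belonged to SPANXB1, a cancer-testis antigen, at 7.37, and to CXCR4, the receptor of the chemokine CXCL12, at 7.27. SPANXB1 read 4.06 in the shRNA control and 11.43 in the shRNA knockdown, and CXCR4 read 3.26 and 10.53. The next were SLAMF7, a lymphocyte surface receptor, at 4.99, PGM5 at 4.59, the pregnancy-specific glycoprotein gene PSG5 at 4.51, and COX7B2, a testis-type subunit of cytochrome c oxidase, at 4.12. The lowest difference was that of the pseudogene AADACP1, at -3.74. Then came the antigen-presentation genes HLA-DRB1 at -3.29, HLA-DRA at -3.21 and HLA-DRB4 at -3.13, followed by the gap junction gene GJB2 at -3.04 and HCLS1 at -3.01. On the shRNA control the 6 highest genes read between 3.13 and 4.06, under the filter level of 4.77, so the size and order of their differences depend on the dim end of the scale, as do AADACP1 and HCLS1 after knockdown. HLA-DRB, PSG and SPANX genes have near-identical copies, and their probe sets can read more than 1 member. With the mean of all probe sets per gene, PGM5 differed by 1.62, PSG5 by 2.34 and HLA-DRB4 by -1.55.

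Across the 15082 genes, 361 were at least 2-fold higher and 313 at least 2-fold lower in the stable knockdown, 674 in all. At 3-fold there were 126 higher and 85 lower. For 73.7% of these 674 genes the shRNA control lay farther from the mean of the siRNA arrays than the shRNA knockdown did, against 56.7% of all genes. The share was 83.7% of the higher and 62.3% of the lower genes. SPANXB1 read 11.70 and 11.50 on the siRNA arrays, CXCR4 10.42 and 10.40, and HLA-DRA 7.76 and 7.45. Without the genes that differed 2-fold between the 2 control arrays, a comparison chosen after the values were seen, 228 of the 674 genes were left, 80 higher and 148 lower. Set against the siRNA control instead, also chosen afterwards, the shRNA knockdown had 1706 genes at 2-fold, 474 higher and 1232 lower.

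The transient knockdown was compared with its luciferase control to find the genes that differ within days of lowering ZEB2. The lowest differences after ZEB2 were those of SCG5, which encodes the secretory granule protein 7B2, at -2.19, ATP6V0D2, a subunit of the vacuolar proton pump, at -1.74, IRAK1BP1 at -1.68, CCND2, a D-type cyclin, at -1.55, and AADACP1 at -1.41. IRAK1BP1 rested on 1 of its 2 probe sets, the other differing by 0.062, and their mean gave -0.81. The highest were MPZL2, an epithelial adhesion protein, at 1.42, LTB, which encodes lymphotoxin beta, at 1.37, and MYH15 at 1.14. AQP3, a water and glycerol channel, followed at 1.09, then HMGN2P46 at 1.06 and PARD6B, a component of the cell polarity complex, at 1.02. With the mean of their probe sets MPZL2 (0.93), LTB (0.73), AQP3 (0.64) and PARD6B (0.40) were short of 2-fold. These 6 and 1 further gene made up the 7 genes at least 2-fold higher, and 19 were at least 2-fold lower, 26 in all. HMGN2P46 rested on 1 cross-hybridising probe set. Without such probe sets 5 genes were at least 2-fold higher and 21 at least 2-fold lower. The standard deviation of the differences over genes was 0.235, against 0.499 in the stable pair. The shRNA pair had 25.9 times as many genes at 2-fold as the siRNA pair, a ratio that depended on the threshold, being 6.66 at 1.5-fold and 52.8 at 3-fold.

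**Figure D1:**
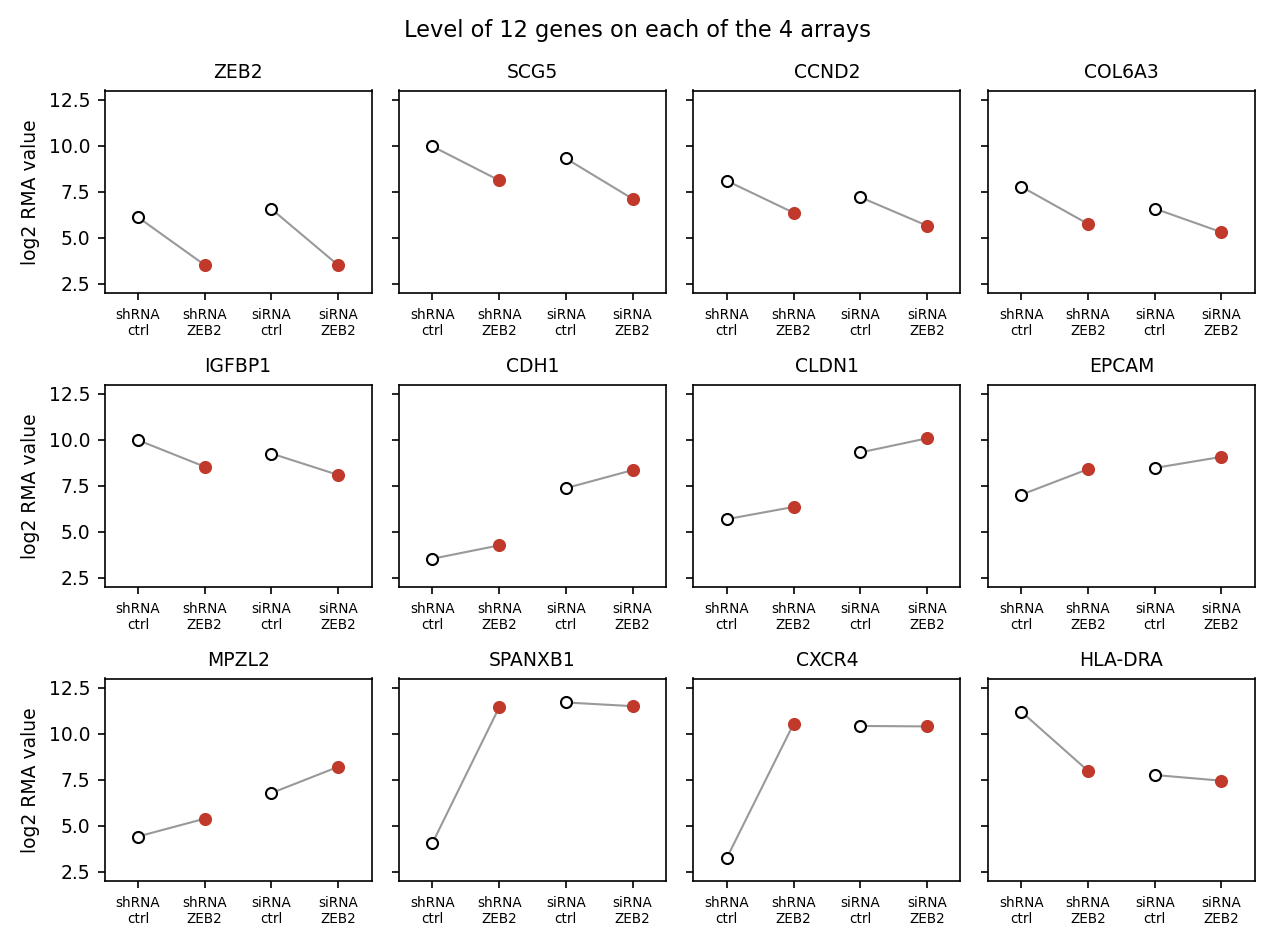
Log2 RMA value of 12 genes on each of the 4 arrays, with open points for controls and filled points for ZEB2 knockdowns, and a line joining the 2 arrays of a pair. ZEB2, SCG5, CCND2, COL6A3 and IGFBP1 were lower in both knockdowns, while SPANXB1 and CXCR4 stood at 4.06 and 3.26 on the shRNA control and above 10 on the other arrays.

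The pairs share no array, so genes that differed the same way in both were sought next. Besides ZEB2, 6 genes were at least 2-fold lower in both knockdowns. SCG5 differed by -1.85 in the shRNA pair and -2.19 in the siRNA pair, CCND2 by -1.73 and -1.55, and AADACP1 by -3.74 and -1.41. COL6A3, a chain of the matrix protein collagen VI, differed by -2.02 and -1.28. IGFBP1, a secreted binding protein of insulin-like growth factors, differed by -1.44 and -1.16, and NDP, which encodes the Wnt receptor ligand norrin, by -1.92 and -1.11. Just short of 2-fold in the siRNA pair were the basal keratin KRT15 (-2.04 and -0.995), the vitamin B12 binding protein gene TCN1 (-1.23 and -0.99) and ADCY10P1 (-1.48 and -0.98). HHIP, an inhibitor of hedgehog ligands, differed by -1.32 and -0.92, and the phospholipase gene PLA2G4A by -1.57 and -0.88. AADACP1 and PLA2G4A were under the filter level on both knockdown arrays, and PLA2G4A on the siRNA control too, at 4.63, so its siRNA difference lay wholly under that level. With the mean of all probe sets per gene in place of the brightest, CCND2 differed by -0.96 and -0.33 and IGFBP1 by -0.83 and -0.52, and in the siRNA pair HHIP differed by -0.54 and ADCY10P1 by -0.52. SCG5, AADACP1, COL6A3 and NDP have 1 probe set each, so averaging could not change them.

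No gene was 2-fold higher in both knockdowns. The nearest was MPZL2, at 0.97 in the shRNA pair and 1.42 in the siRNA pair. Of the 12 highest, CDH1 and CLDN1 belong to the epithelial junction list. CDH1, which encodes E-cadherin, differed by 0.73 and 0.98, the tight junction gene CLDN1 by 0.66 and 0.77, PARD6B by 0.66 and 1.02, and PPL, which encodes the desmosome-linked protein periplakin, by 0.74 and 0.93. CDH1 read 3.54 and 4.26 on the shRNA arrays, under the filter level, and 7.37 and 8.35 on the siRNA arrays. The scaffold gene NEDD9 differed by 3.31 and 0.74, the receptor gene TNFRSF9 by 1.19 and 0.71, and AQP3 by 0.65 and 1.09. The others were the growth factor gene NRG1 (0.81 and 0.83), ZNF506 (0.99 and 0.78), SERTAD4 (0.77 and 0.77) and PDE5A (0.66 and 0.68). Other PDE5A probe sets lay between -0.23 and 0.22 in the shRNA pair and between -0.08 and 0.69 in the siRNA pair. NRG1 depended on the probe set, since the mean of its 6 probe sets gave -0.30 and 0.02. Means of probe sets were also smaller for MPZL2 (0.50 and 0.93), AQP3 (0.21 and 0.64), TNFRSF9 (0.47 and 0.42), ZNF506 (0.60 and 0.21) and NEDD9 (1.17 and 0.51), for PARD6B in the siRNA pair (0.40) and for CDH1 in the shRNA pair (0.44).

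Independent lists of the same lengths would share 0.394 genes lower and 0.168 genes higher, against 7 and 0 observed. At 1.5-fold, 50 genes were lower and 19 higher in both pairs, against 16.2 and 7.85. The 7 and the 50 include ZEB2, which both knockdowns target, so its place in them was fixed by the design. Without ZEB2, 6 genes shared a direction at 2-fold. Opposite directions were also more frequent than independent lists give. At 1.5-fold, 51 genes were higher in the shRNA pair and lower in the siRNA pair, against 17.2, and 10 were lower and then higher, against 7.4. Over all genes the differences of the pairs were unrelated, with Pearson r = 0.00191 and Spearman rho = -0.0243 across genes, which are not independent replicates.

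A common knockdown effect was tested with limma over all 4 arrays, with the method as a block, which treats the 2 methods as replicates of ZEB2 loss and leaves 1 residual degree of freedom. ZEB2 had a mean difference of -2.82 ± 0.18 (SE) and an unadjusted p of 0.000127 in limma, and SCG5 had -2.02 ± 0.19 and 0.000511. CCND2 followed with -1.64 ± 0.16 and 0.000608. After Benjamini-Hochberg adjustment over all genes, the smallest adjusted p from limma was 0.971, and 0 genes passed. At an unadjusted p under 0.05, limma gave 384 genes, where 754 are expected by chance. On simulated data with the spread of these arrays, the same limma step recovered 0% of genes changed 2-fold, 43.3% of those changed 4-fold and 90.9% of those changed 8-fold. ZEB2, at -2.60 in the shRNA pair and -3.05 in the siRNA pair, still had an adjusted p of 0.971 in limma. The simulated rates for large changes therefore do not carry over to these arrays. Smaller shared effects were not detectable here, and 0 genes passing does not exclude large ones.

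**Figure D2:**
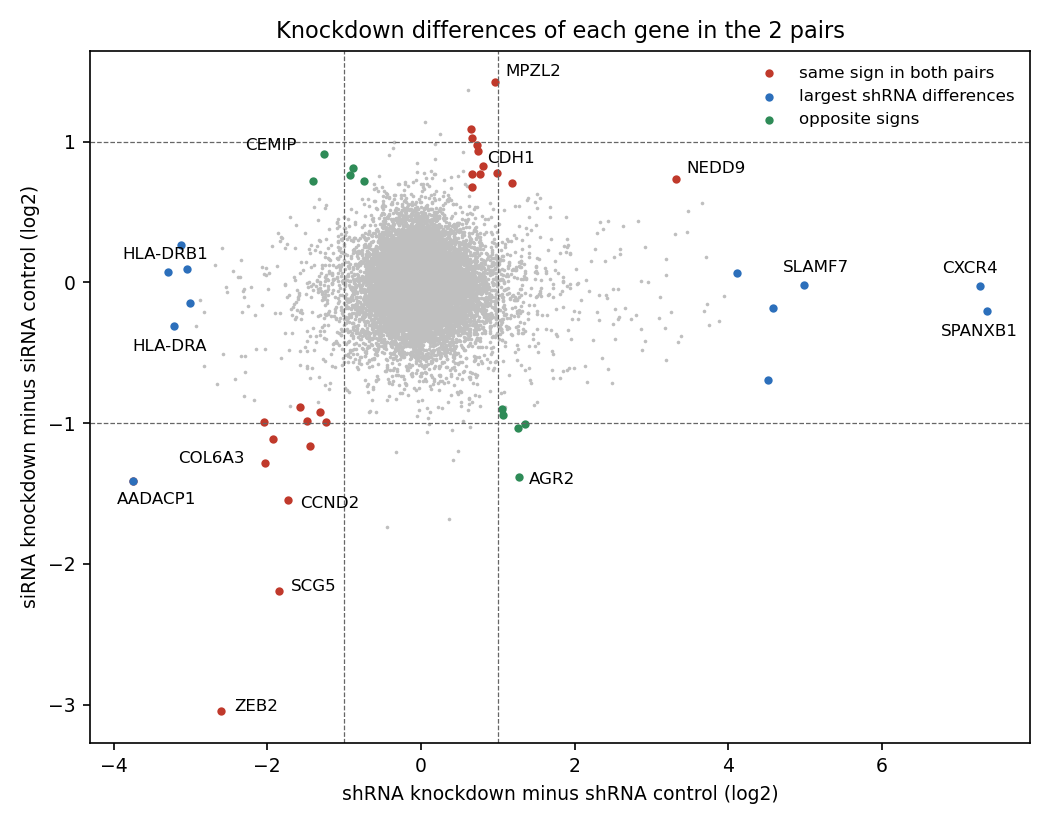
Knockdown minus control in the shRNA pair (x axis, log2) against the siRNA pair (y axis, log2) for each of the 15082 genes, with dashed lines at 2-fold. The cloud is wider along the x axis, and ZEB2, SCG5, CCND2, AADACP1 and COL6A3 lie at least 2-fold lower in both pairs.

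Some genes differed in opposite directions in the pairs. AGR2, a luminal secretory protein, was higher by 1.28 in the shRNA pair and differed by -1.38 in the siRNA pair. TAF12 (1.27 and -1.03) and EHD3 (1.35 and -1.002) were the other genes at 2-fold in opposite directions, 3 in all, against 0.6 for independent lists. ASB2 (1.07 and -0.95) and the protease gene PAPPA (1.05 and -0.90) came next. In the other sense, the hyaluronan-degrading protein gene CEMIP differed by -1.26 and 0.91, and ID2, an inhibitor of basic helix-loop-helix factors, by -0.89 and 0.82. TMEM64 (-0.92 and 0.77), PABIR2 (-0.74 and 0.72) and ZNF804A (-1.40 and 0.72) followed. Without cross-hybridising probe sets PABIR2 differed by -0.19 and -0.081, the same sign in both pairs. The mean of all probe sets gave 0.79 and -1.12 for AGR2 and 0.45 and -0.39 for EHD3. TAF12, with 1 probe set that averaging cannot change, was left as the only gene at 2-fold in both. The mean also gave smaller differences for PAPPA (0.23 and -0.43) and CEMIP (-0.83 and 0.57), and in the siRNA pair for ASB2 (-0.46), TMEM64 (0.47) and PABIR2 (0.32). None of these gaps between the pairs could be tested.

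Genes of the core EMT panel, which holds epithelial and mesenchymal genes together, had no common direction in the siRNA pair. Of its 12 genes measured, 8 were higher and 4 lower in the shRNA pair, and 6 and 6 in the siRNA pair. The panel's median difference was 0.445 in the shRNA pair (percentile 100 among random lists) and 0.00825 in the siRNA pair (percentile 62.1), the latter turning below 0 under each of the 3 other scalings. It was also higher in the siRNA control than in the shRNA control, both of which keep ZEB2, with a median of 0.779 (percentile 99.9). EPCAM, an epithelial adhesion molecule, was higher by 1.39 in the shRNA pair and 0.60 in the siRNA pair. Opposite signs were seen for the EMT repressor gene SNAI2, at 1.97 and -0.26, and for the matrix gene FN1, at 0.54 and -0.98. The mesenchymal genes VIM and CDH2 differed by -0.15 and -0.15 and by 0.45 and -0.23, and ZEB1, the paralog of ZEB2, by -0.28 and 0.13. SNAI1 (-0.58 and 0.19), CLDN4 (0.44 and -0.05), OCLN (0.56 and 0.06), CD44 (-0.38 and 0.08) and MMP1 (0.31 and -0.57) made up the rest, and TWIST1 and ESRP1 were under the filter level on every array. CD44 turned to 0.10 in the shRNA pair with the mean of its 13 probe sets, and CLDN4 to 0.05 in the siRNA pair, where FN1 differed by -0.61. Epithelial junction genes were higher on balance in both knockdowns. Of 38 measured, 23 were higher and 15 lower in the shRNA pair, with a median of 0.114 (percentile 98.4). In the siRNA pair 25 were higher and 13 lower, with a median of 0.0925 (percentile 99.8). The count higher in both pairs was 14, where the product of the 2 shares gives 15.1. Beside CDH1, CLDN1 and EPCAM, the polarity gene PATJ differed by 1.27 and 0.54. Its other probe sets lay between -0.12 and 0.28 in the shRNA pair. Of the list, 4 genes were at least 2-fold higher in the shRNA pair and 2 at least 2-fold lower, CLDN7 (-1.25) and MYO5B (-1.53). The same list was also higher in the siRNA control than in the shRNA control, with a median of 0.564 (percentile 100). With the mean of all probe sets per gene its median in the siRNA pair was 0.034 (percentile 92.7).

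Mesenchymal markers were higher in the shRNA pair, with a median of 0.324 over 26 genes (percentile 100), 16 higher and 10 lower. They lay at 0.000531 in the siRNA pair (percentile 62.5), 13 higher and 13 lower. In the siRNA control they were higher than in the shRNA control by a median of 0.254 (percentile 92.2). Their examples were the calcium-binding protein gene S100A4 (1.92 and 0.27) and the collagen cross-linking enzyme gene LOX (2.36 and -0.54). The EMT transcription factors, 7 measured and ZEB2 among them, had medians of -0.453 (percentile 0.4) and -0.0886 (percentile 16.3). ZEB2 is the target of both knockdowns, so its fall was fixed by the design, and both medians count it. In the shRNA pair 1 was higher and 6 lower, and in the siRNA pair 3 higher and 4 lower, ZEB2 among the lower each time. The sign of the siRNA median therefore leans on counting ZEB2. Adjusted over the list alone, limma called 1 of these 7 genes, the target ZEB2, with an adjusted p of 0.000887, and 0 genes in each of the other 23 lists. That call tells nothing about the other factors. Over all genes tested, limma called 0 members of any list.

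Matrix and adhesion genes went both ways. Collagens, laminins and other matrix genes had medians of 0.105 (percentile 94.6) and 0.0403 (percentile 96.9) over 34 genes, with COL6A3 lower by at least 2-fold in both pairs. Matrix proteases and their inhibitors had medians of -0.111 (percentile 5.67) and 0.0135 (percentile 68.3) over 27 genes. Among them the protease gene ADAMTS1 differed by 2.80 and -0.23 and the inhibitor gene TIMP1 by -1.32 and -0.23. Integrins had medians of -0.169 (percentile 6.25) and 0.0721 (percentile 94.2) over 15 genes, with ITGB2 at 2.41 and -0.09 and ITGA2 at -1.48 and -0.000257. Basal breast markers had medians of 0.0707 (percentile 82.4) and 0.146 (percentile 98.6) over 14 genes, with TRIM29 at 1.30 and 0.15 and KRT15 lower in both. Luminal markers had medians of 0.148 (percentile 96) and -0.0222 (percentile 46.8) over 17 genes, with CD24 at 3.66 and 0.57 and the receptor gene ERBB3 at 1.87 and 0.26. Breast stem-like markers had medians of -0.16 (percentile 9.31) and 0.0881 (percentile 94.7) over 10 genes, with the aldehyde dehydrogenase gene ALDH1A3 at -2.30 and -0.05. In the shRNA pair the mean of all probe sets gave 1.55 for ITGB2, 0.59 for TRIM29, 0.65 for ERBB3 and -1.31 for ALDH1A3.

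DNA replication genes were lower in the stable knockdown and slightly higher in the transient one. Of 33 measured, 31 were lower in the shRNA pair, with a median of -0.397 (percentile 0), and 23 were higher in the siRNA pair, with a median of 0.0777 (percentile 99.8). The count higher in the siRNA pair was 19 under median centring and 27 under quantile normalization. DNA replication genes were also lower in the siRNA control than in the shRNA control, with a median of -0.813 (percentile 0). The polymerase gene POLA1 (-0.64 and -0.30) and the replicative helicase subunit gene CDC45 (-0.62 and -0.12) were lower in both. Mitosis genes had medians of -0.0768 (percentile 16.1) and 0.0814 (percentile 99.8) over 30 genes, with KIF20A at 0.73 and 0.18 and CENPA at 0.52 and 0.28. No gene of either list reached 2-fold in either pair. Cell cycle inhibitors and p53-linked genes had medians of 0.0476 (percentile 80.4) and -0.0259 (percentile 65) over 24 genes, with the p53 antagonist gene MDM2 at -1.81 and 0.32 and the stress cytokine gene GDF15 at 1.69 and -0.34. MDM2 differed by -0.53 and -0.09 when its probe sets were averaged, a turn of sign in the siRNA pair, and GDF15 by 0.73 in the shRNA pair.

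Cholesterol synthesis genes and the ATF4 stress response were higher in the stable knockdown and lower in the transient one. Of 18 cholesterol genes, 16 were higher in the shRNA pair, with a median of 0.406 (percentile 100), and all 18 were lower in the siRNA pair, 16 under cyclic loess and 13 under quantile normalization, with a median of -0.282 (percentile 0). INSIG1, a sterol sensor partner, differed by 1.71 and -0.51, and the synthase gene LSS by 1.46 and -0.36. Of 28 unfolded protein and ATF4 response genes, 19 were higher in the shRNA pair, with a median of 0.509 (percentile 100), and 26 were lower in the siRNA pair, with a median of -0.27 (percentile 0). ASNS, which makes asparagine, differed by 2.88 and -0.48, and the stress-induced gene DDIT4 by 2.43 and -0.61. Both lists were also higher in the siRNA control than in the shRNA control, with medians of 1.10 and 0.931 (percentile 100 each). Hypoxia and glycolysis genes had medians of 0.247 (percentile 99.8) and -0.000692 (percentile 65.4) over 29 genes, with ADM at 2.40 and 0.15 and ANGPTL4 at -1.62 and -0.24. Ribosomal protein genes had small medians of 0.142 (percentile 87.1) and -0.0871 (percentile 0.6) over 20 genes. Of these, 19 were higher in the shRNA pair and 18 lower in the siRNA pair, 17 and 18 under quantile normalization and under cyclic loess. RPL11 differed by 0.47 and -0.06, and RPLP2, 1 of the 2 genes higher in the siRNA pair, by 0.24 and 0.21. Taking the mean of probe sets gave 1.44 for ASNS and -0.10 for RPLP2 in the shRNA pair and 0.01 for ANGPTL4 in the siRNA pair.

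Interferon-stimulated genes were lower in the stable knockdown. Of 44 measured, 36 were lower, 12 of them by at least 2-fold, and the median was -0.509 (percentile 0). The siRNA pair had a median of -0.0618 (percentile 23.1), with 30 lower. In the siRNA control these genes were higher than in the shRNA control, with a median of 0.935 (percentile 100). OASL, an antiviral protein gene, differed by -2.15 and -0.47, and SAMD9 by -1.59 and -0.07. NF-kB and cytokine genes were split 16 to 16 in each pair, with medians of 0.0165 (percentile 71.3) and -0.0222 (percentile 54.4). Their examples were the interleukin genes IL6 (1.52 and 0.63) and IL24 (1.78 and 0.07). TGF-beta and BMP targets had medians of -0.156 (percentile 3.61) and -0.0152 (percentile 62.6) over 30 genes. The activin subunit gene INHBA differed by 3.19 and -0.55, and ID1, a direct BMP target, by -2.44 and 0.08. Wnt pathway genes had medians of -0.029 (percentile 42.7) and 0.0581 (percentile 90.5) over 24 genes, with LEF1 at -1.82 (-0.71 with the mean of its probe sets) and -0.54 and WNT5A at 1.89 and 0.22. The other WNT5A probe set differed by 0.89 and -0.53.

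Markers of other cell types were followed as a check on what the cultures held. Leukocyte markers had medians of -0.224 (percentile 3.34) and 0.0829 (percentile 74.7) over 10 genes. Among them CD74 differed by -1.35 and 0.02 and LYZ by -1.19 and 0.17. LYZ read 4.70 and 3.51 on the shRNA arrays, so its shRNA difference lay wholly under the filter level. Its other probe set differed by -0.06 in the shRNA pair and by 0.09 in the siRNA pair. Endothelial markers had medians of -0.455 (percentile 0.08) and 0.0903 (percentile 85.2) over 8 genes, with ESAM at -1.41 and -0.05 and KDR at 0.91 and 0.08. Fibroblast markers had medians of 0.243 (percentile 95.8) and 0.0871 (percentile 81.5) over 6 genes, with the matrix proteoglycan gene LUM at 3.89 and -0.28 (2.03 and 0.01 with the mean of its probe sets) and PDGFRB at 0.50 and 0.13. Several genes of these lists are also expressed by mesenchymal-like carcinoma cells.

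**Figure D3:**
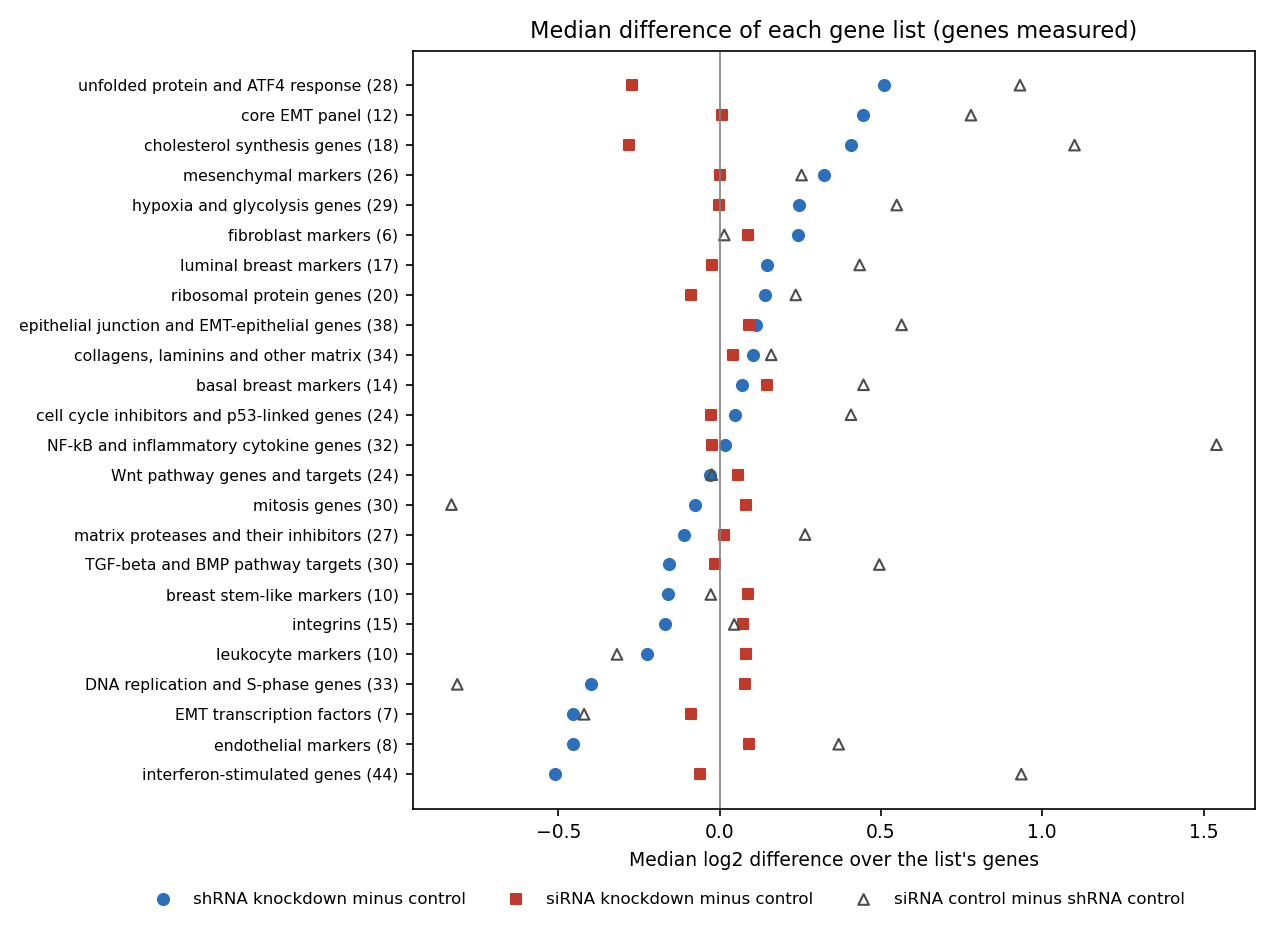
Median log2 difference of each of the 24 gene lists, with the number of genes measured in brackets, for the shRNA pair (circles), the siRNA pair (squares) and the siRNA control minus the shRNA control (triangles). Unfolded protein and ATF4 response genes and cholesterol synthesis genes lie above 0 for the shRNA pair and below 0 for the siRNA pair, and the triangles lie farther from 0 than the squares for most lists.

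Both control arrays keep ZEB2, so the difference between them shows how far apart the cultures and methods stood without knockdown. UCA1, a long noncoding RNA, was higher in the siRNA control by 8.22, SPANXB1 by 7.64, CXCR4 by 7.16, SLAMF7 by 7.12 and the cytokine gene TNFSF15 by 6.66. Lower in the siRNA control were ID1 at -4.89, ADGRF1 at -3.90, RNF128 at -3.87, NAA15 at -3.86 and AKAP12 at -3.84. In all, 1625 genes were at least 2-fold higher and 752 lower in the siRNA control, 2377 together. The balance depended on the probe sets. Their mean per gene gave 1068 higher and 822 lower, and single probe sets gave 2662 higher and 2959 lower. NF-kB and cytokine genes had a median of 1.54 (percentile 100), with 22 of 32 at least 2-fold higher. Mitosis genes had a median of -0.831 (percentile 0).

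RNA labelling also differed between the methods, with 2 micrograms of total RNA for the shRNA arrays and 100 ng for the siRNA arrays, so labelling, culture and method cannot be told apart in the comparison of the controls. The beta-actin 3' minus 5' signal was -0.038 and -0.033 on the shRNA arrays and 0.498 and 0.521 on the siRNA arrays, and probe sets for 18S ribosomal RNA averaged 8.32, 8.12, 10.7 and 10.9 in the same order. Across the genes kept, the siRNA arrays correlated at r = 0.994 with each other and the shRNA arrays at r = 0.974. The shRNA knockdown correlated more with the siRNA control (r = 0.952) than the shRNA control did (r = 0.928). Differences of the shRNA pair and of the controls correlated at r = 0.572 over genes. They share the shRNA control array, and their covariance was 0.235, where the noise of 1 shared array, estimated from the siRNA pair, gives 0.0276.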

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

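Every test in this part was chosen after the result was seen, except the choice of probe set for the epithelial list, which was set beforehand. All gaps between the pairs given here were not tested, since each pair has 1 array per group.

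The shRNA pair held 25.9 times as many genes at 2-fold as the siRNA pair, 6.66 times at 1.5-fold and 52.8 times at 3-fold. Unequal RNA degradation is argued against, because the beta-actin 3' minus 5' signal differed by 0.00473 between the shRNA arrays, against 0.536 between the controls. For a single admixed share of siRNA-like cells, 48 genes implied shares from 0.945% at their 10th percentile to 96.8% at their 90th. This spread cannot decide the question, because the shares compare arrays that differed in labelling. They also rest on genes under the filter level on the shRNA control. Genes higher in the shRNA pair, with a median of 1.37, had -0.0813 in the siRNA pair (random lists -0.054 to -0.00527). The lower genes, with a median of -1.29, had -0.062 (random lists -0.0543 to -9.22e-05), the same direction but far smaller. The siRNA culture thus did not show these changes within the time of the transient knockdown. Many of the higher genes, such as SPANXB1 (11.70) and CXCR4 (10.42), already stood near their shRNA knockdown level on the siRNA control, with ZEB2 present. Whether such genes could rise further there was not tested, and values on the siRNA control reached 14.6. The siRNA culture started from other levels of such genes than the shRNA control did. For the 2-fold genes of the shRNA pair, the comparison therefore cannot decide whether ZEB2 loss acted in the shRNA culture. The shRNA control lay farther from the siRNA arrays than the shRNA knockdown did for 73.7% of these genes, against 56.7% of all genes, which is consistent with a control array that stands apart, mostly for the higher genes (83.7%) and less for the lower ones (62.3%). Slower effects of lasting ZEB2 loss, selection of the transduced cells and drift or origin of the control culture were not tested and remain open. This list is not complete. Poly-A control spikes differed by -0.68 between the shRNA arrays and by -0.16 between the siRNA arrays, and unequal RNA input or labelling within the shRNA pair was not tested.

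Besides ZEB2, 6 genes were 2-fold lower in both pairs and 3 were 2-fold in opposite directions, too few to separate ZEB2 loss from genes that vary between any arrays. At 1.5-fold, 61 genes went opposite ways and 68 besides ZEB2 went the same way, so variable genes could account for part of the shared set.

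Epithelial junction genes were higher on balance in both pairs. The siRNA pair holds no shRNA array, but its percentile of 99.8 (100 between the controls) is the observation itself and tests nothing further about the shRNA control. With the mean of all probe sets the median in the siRNA pair was 0.034, and the percentile was 92.7 in the siRNA pair and 99.1 in the shRNA pair, so whether the choice of probe set matters cannot be told apart from a true shift in the siRNA pair. The 14 genes higher in both pairs did not exceed the 15.1 that unlinked members give, so the same genes may not underlie the 2 medians.

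Opposite directions in the pairs were seen for AGR2 (1.28 in the shRNA pair and -1.38 in the siRNA pair), TAF12 (1.27 and -1.03), EHD3 (1.35 and -1.002), ASB2 (1.07 and -0.95) and PAPPA (1.05 and -0.90), the difference between the pairs not being tested. CEMIP (-1.26 and 0.91), ID2 (-0.89 and 0.82), TMEM64 (-0.92 and 0.77), PABIR2 (-0.74 and 0.72) and ZNF804A (-1.40 and 0.72) went the other way, also untested. Without cross-hybridising probe sets PABIR2 had the same sign in both pairs (-0.19 and -0.081). AGR2 (0.79 and -1.12) and EHD3 (0.45 and -0.39) were no longer 2-fold in both pairs with the mean of probe sets. TAF12 has 1 probe set, so the mean could not change it. The list medians of DNA replication genes (-0.397 and 0.0777), cholesterol synthesis genes (0.406 and -0.282) and unfolded protein and ATF4 response genes (0.509 and -0.27) had opposite signs too, and their gaps were not tested.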

How the results depend on the processing

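The causes of the shifts below were not tested, apart from thresholds and sets of genes, which change a count by construction. Settings that left out genes differing 2-fold between the controls, or that set the shRNA knockdown against the siRNA control, were chosen after seeing the data. Genes at 2-fold in the shRNA pair (674) numbered 1351 of 29214 probe sets when each was taken on its own, a change of unit from the 15082 genes, 2211 at 1.5-fold, 211 at 3-fold, 228 without genes that differ between the controls and 1706 against the siRNA control. In the siRNA pair (26) the numbers were 13 with the mean of probe sets, 71 probe sets, 332 at 1.5-fold, 4 at 3-fold and 9 without genes that differ between the controls. Genes sharing a direction (7) numbered 4 with the mean of probe sets, 69 at 1.5-fold, 2 at 3-fold and 4 without genes that differ between the controls, and cyclic loess gave 1 higher and 7 lower. The 4 left by the mean, SCG5, AADACP1, COL6A3 and NDP, have 1 probe set each, so the mean could not change them. Opposite genes (3) numbered 1 with the mean of probe sets, 5 probe sets, 1 under quantile normalization, 61 at 1.5-fold, 0 at 3-fold and 0 without genes that differ between the controls. TAF12, the gene left by the mean, also has 1 probe set. Between the controls (2377) there were 5621 probe sets, 2662 higher and 2959 lower, 5132 at 1.5-fold and 854 at 3-fold, and the mean of probe sets gave 1068 higher and 822 lower. The ZEB2 difference was -0.73 in the shRNA pair and -0.84 in the siRNA pair with the mean of its 5 probe sets, -1.33 and -1.50 for the next brightest probe set, and 0.095 and -0.083, 0.13 and 0.42, and 0.030 and 0.022 for the 3 dim ones. NRG1 turned to -0.30 and CD44 to 0.10 in the shRNA pair with the mean of probe sets, and PABIR2 to -0.081 in the siRNA pair without cross-hybridising probe sets. Of 1718 recomputed differences of named genes, 1680 moved by less than 1.5-fold, 36 moved by more, and 2 that were at least 1.5-fold reversed. Many of the 1718 could not move, so the 1680 are no measure of stability. The filter settings leave a gene's difference as it is, and averaging does so for a gene with 1 probe set. Among the 1680, 17 took the other sign, each reported under 1.5-fold. For 63 named genes with several probe sets, their mean shrank 47 of 79 differences of at least 1.5-fold by over 1.5 times or reversed them. ZEB2, PDE5A, PATJ, WNT5A and LYZ also have several probe sets and were not in this count. Of 288 recomputed list medians, 252 stayed and 36 moved, and 14 of the 48 medians changed sign under some alternative, none of them over 0.0903 in size. In every setting limma called 0 genes, with a smallest adjusted p between 0.305 under quantile normalization and 1 without the method block, which gave 40 genes at an unadjusted p under 0.05. Dim signal limits, among others, ZEB2, AADACP1 and HCLS1 after knockdown, PLA2G4A there and on the siRNA control, CDH1 on the shRNA arrays and the 6 highest genes of the shRNA pair on their control.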

Other observations

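Gene families that the lists did not hold were looked at after their values were seen. MHC class II genes, which present antigen on the cell surface, were lower in the stable knockdown. Of 12 such genes measured, 8 were at least 2-fold lower, with a median difference of -1.71 in the shRNA pair and -0.0403 in the siRNA pair. Beside HLA-DRA and HLA-DRB1, HLA-DPA1 differed by -2.82, HLA-DPB1 by -2.31, HLA-DMA by -1.57 and HLA-DMB by -1.43 in the shRNA pair. CD74, the invariant chain of the same pathway, differed by -1.35, and CIITA, the transactivator of these genes, by -0.52. Leukocyte markers, CD74 among them, were lower with these genes in the shRNA pair, 9 of 10 with a median of -0.224 (percentile 3.34), and so was HCLS1, a blood-cell gene, at -3.01. The siRNA control was also lower than the shRNA control for 11 of the 12, with a median of -1.54, so the shRNA control held the highest level for most of the family. The median in the shRNA pair stayed below 0 under the 3 other scalings. Near-identical copies among the HLA-DRB genes leave their separate values uncertain.

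Pregnancy-specific glycoprotein genes, normally products of the placenta, were higher in the stable knockdown for all 9 measured, 7 of them by at least 2-fold, with a median of 2.00. All 9 were lower in the siRNA knockdown, with a median of -0.424, and both medians kept their sign under the 3 other scalings. PSG4 differed by 3.34 and -0.42, PSG9 by 2.92 and -0.42, and PSG1 by 2.57 and -0.26. These paralogs are nearly identical and most of their probe sets cross-hybridise, so the family counts as few independent measurements. Without cross-hybridising probe sets 4 genes were left, with medians of 0.523 and 0.0605.

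Poly-A control spikes, added to the RNA before labelling, averaged 8.36 on the shRNA control and 7.69 on the shRNA knockdown, and 8.53 and 8.37 on the siRNA arrays. Hybridisation spikes averaged 10.8, 10.7, 10.7 and 10.6 in the same order. The 3' minus 5' signal of GAPDH was -0.074, -0.071, 0.115 and 0.187.

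The 361 genes at least 2-fold higher in the shRNA pair had the same sign in the siRNA pair in 146 cases (40.4%), and the 313 lower genes in 186 cases (59.4%). In the reverse direction, the 7 genes at least 2-fold higher in the siRNA pair had a median of 0.609 in the shRNA pair, where random lists of that size gave -0.322 to 0.315, and 6 of the 7 had the same sign. The 18 lower genes other than ZEB2 had a median of 0.0983, within the random range of -0.195 to 0.139. At 1.5-fold, the 104 higher genes had a median of 0.0522 (random -0.101 to 0.0335) with 55.8% of the same sign. The 227 lower genes other than ZEB2 had 0.0557, outside the random range of -0.0793 to 0.0166 in the opposite direction, with 46.7% of the same sign.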
